A study of Homo sapiens with 30 samples.

How the data were processed

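RNA from Rh30 cells, an established alveolar rhabdomyosarcoma line that carries the PAX3-FOXO1 fusion, was measured by RNA sequencing in 30 samples that form 15 groups of 2. Per the labels' protocols, cells were grown in RPMI-1640 with a serum substitute and total RNA was taken with TRIzol. A tagged line carries a degradation tag (FKBP) on either PAX3-FOXO1 or FOXO1, and the small molecule dTAG, given here at 500 nM, directs the tagged protein to the proteasome. No protein was measured here, so fusion loss stands for dTAG given to the PAX3-FOXO1-FKBP line. The time-course samples are 20, from 2 lines kept in DMSO or in dTAG for 2, 6, 24 or 72 h. The other 10 libraries are untreated parental Rh30 and the PAX3-FOXO1-FKBP clones 4, 10, 11 and 12. Which clone, if any of these, is the PAX3-FOXO1-FKBP time-course line is not given in the sources used here. Nothing in the labels says whether the 2 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

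The submitters' processing notes name Trimmomatic 0.32, Bowtie2, Cuffdiff 2.1.1 and the genome build hg19. Their roles, the Bowtie2 version, the gene annotation and the tool that counted the clone libraries are not given in the sources used here. The time-course tables hold estimated counts deposited by the authors, with 1 column per condition per the file headers. The 2 replicates of a condition were thus pooled by the authors, 73.6% of the values are not whole numbers, and any scaling between conditions is not given in the sources used here. The clone table holds raw read counts deposited by the authors, as whole numbers with 1 column per library. The time-course tables list 23262 genes and 23261 are in that of the clones. Totals were 25863451 to 30466960 per time-course column and 17746684 to 26834005 per clone library. Gene names are used as the tables give them. GC content and transcript length came from GENCODE v29, which is built on another assembly than hg19, so no coordinates are printed. Gene order came from RefSeq gene records. Both were matched by gene symbol. Of the 23262 time-course symbols, 19576 were found in a separate list of gene names.

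The clone libraries were tested with edgeR 4.0.16 (R 4.3.3) quasi-likelihood F tests on all 10 libraries with 1 mean per group, TMM scaling and the filterByExpr filter (minimum count 10), which leaves 5 residual degrees of freedom. Calls needed a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are on the log2 scale. Those of the time course used a prior count of 2. Those of the edgeR tests used the smaller default prior of that tool, which gives larger changes for genes near 0 counts. Where a group had no counts, a bound was computed against 3 counts per library, and such bounds cover counting error only.

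The design had assumed time-course counts per library. With 1 pooled column per condition a test at each time has no replicate check, so a rule of size took its place after the data were seen: at least 2-fold against DMSO with a mean normalised count of at least 50 over the 5 columns of the line. Normalised counts are scaled with TMM factors. Genes with an exact 0 in 1 or more columns where the other columns held at least 10 counts were left out as failed estimates, EEF1A1 among them. A trend test was added after the data were seen. It fits an edgeR quasi-likelihood slope on log2 of hours plus 1 over the 5 columns of a line (counts rounded to whole numbers, 3 residual degrees of freedom), and over both lines for the difference in slope (6 residual degrees of freedom). Its p-values measure scatter of pooled columns around a straight line, not replicate error. "Rose" and "fell" are used of time-course genes only where this test passed, and "higher" or "lower" describes the columns.

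Before the data were examined, the groups, the clone tests, the alternatives, the rule for named genes and 24 gene lists had been fixed. The lists cover published PAX3-FOXO1 targets, myogenic transcription factors, muscle contractile and differentiation genes, S phase, G2/M, ribosome biogenesis and MYC-responsive genes, FOXO-responsive genes, ERK feedback and immediate-early genes, p53-responsive genes, the BCL2 family, the Notch pathway, YAP/TEAD-responsive, neuronal, extracellular matrix and fibroblast, ATF4-responsive, cholesterol synthesis, hypoxia-responsive, interferon-stimulated and heat shock genes, markers of epithelial, blood and endothelial cells, replication-dependent histone mRNAs and mitochondrially encoded mRNAs. The published targets were collected from general knowledge of the fusion. Named genes are PAX3 and FOXO1, then the 6 with the largest change each way per contrast among the called genes with a mean of at least 50, up to 10 changed at all 4 times, and up to 4 called members of each list by lowest p, or its lowest-p members where fewer passed. LOC, antisense, read-through, histone and ribosomal protein names were left out. In the time course size stood in for the p of this rule and the trend test ranked list members. Lists of B lineage, pan-leukocyte, T lineage, myeloid and erythroid genes were written after B-cell genes had been seen in 1 column.

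Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, which tests direction without comparing a list with other genes. The time-course lists were also described by their median at each time and its percentile among 10000 random lists matched on mean expression in 25 bins. The genes at least 2-fold lower or higher at 6 h in the PAX3-FOXO1-FKBP line were then tested in the clones and in the FOXO1-FKBP line. Times share their DMSO column, so persistence over time was set beside 100 simulations of unchanged groups against that column. Their noise came from the spread of the clone libraries at the same mean, as for 2 libraries summed. It was independent between genes and may differ from that of the time-course columns.

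The tests were tested on simulated data with 200 planted genes. In the clone design (13638 genes) 25.4 to 31.3% of 1.5-fold, 83.6 to 92.5% of 2-fold and 100% of 4-fold changes were recovered, with 4.64 to 6.88% of calls false. The trend test recovered 83.6% of 2-fold changes in the PAX3-FOXO1-FKBP line (12335 genes), 88.1% in the FOXO1-FKBP line (11982 genes) and 52.2% for the line difference (11767 genes). Its planted changes were straight on the fitted time scale. The size rule at 6 h (12334 genes) recovered 52.2% of 2-fold and 100% of 4-fold changes with 9 false calls. Simulated noise was independent between genes. Real replicate pairs differed along transcript length (rho = 0.666 in clone 4) and GC content (rho = -0.655 in clone 11). The simulated rates are thus best cases. Replicate pairs of the clone table were compared by a chi-square over genes and all differed by more than sampling noise, with 1.894 per gene in the parental pair and 15.79 to 60.17 in the clones. Alternatives were DESeq2 1.42.0, RLE size factors, library totals, other count filters, GC and length correction, a replicate block, fits on 4 libraries, each library left out and, for the trend, other time sets. Some withheld genes are not reported here. XIST and Y-linked genes were left out of all gene tables, and time-course tests per library were not run because the columns are pooled.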

Results

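The series asks what PAX3-FOXO1, the fusion transcription factor of alveolar rhabdomyosarcoma, keeps on or off in Rh30 cells, with a tag meant to degrade it quickly and RNA followed over time. Total estimated counts in the PAX3-FOXO1-FKBP line were 29595555 in DMSO and 30466960, 28780426, 27561650 and 29587221 at 2, 6, 24 and 72 h of dTAG. In the FOXO1-FKBP line, which answers for the compound and for loss of tagged wild-type FOXO1, they were 26555143 in DMSO and then 26324319, 25999630, 25863451 and 27381073. Each time-course column pools 2 samples, so its values carry no replicate error. Untreated libraries held 23773431 and 26834005 counts in parental Rh30, 19770435 and 19556442 in clone 4, 22747634 and 19159020 in clone 10, 24560297 and 17746684 in clone 11, and 18294367 and 21912607 in clone 12.

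PAX3 mRNA, which includes the PAX3 part of the fusion transcript, was lower at every time after dTAG in the PAX3-FOXO1-FKBP line. Its log2 change was -0.69, -0.96, -0.66 and -0.96 at 2, 6, 24 and 72 h, from 781.4 normalised counts in DMSO. In the FOXO1-FKBP line PAX3 stayed at -0.08, 0.02, 0.37 and -0.17. FOXO1 mRNA, which likewise includes the fusion's part, was at -0.16, 0.13, 0.53 and 0.30 in the first line and at -0.02, -0.00, 0.03 and -0.09 in the second. dTAG acts on protein, so neither mRNA checks the labels.

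The 6 largest decreases at 2 h of dTAG in the PAX3-FOXO1-FKBP line lay between -1.36 and -1.79 (log2). HS3ST3B1, a heparan sulfate sulfotransferase, was at -1.79, TACR3, the neurokinin B receptor, at -1.66, and CNR1, a cannabinoid receptor and published fusion target, at -1.36 (log2). PROX1, a homeobox transcription factor, was at -1.51, the mucin MUC2 at -1.39 and the SNARE protein STX11 at -1.36. TACR3 and PROX1 were also lower in the FOXO1-FKBP line at 6 h (-0.59 and -0.58) and 72 h (-1.13 and -1.41), with PROX1 at 1.10 at 24 h. In that line at 72 h MUC2 was at 0.09, STX11 at -0.03 and CNR1 at -0.35. In the PAX3-FOXO1-FKBP line at 2 h, 46 of 12334 genes were at least 2-fold higher and 35 lower. Scaled by library totals, 40 were higher and 46 lower.

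The 6 largest increases at 2 h were of 4 B lineage genes, the leukocyte gene LCP1 and LAYN. IGJ, the immunoglobulin joining chain, went from 0 to 377 normalised counts, LCP1, a leukocyte actin bundler, from 1.8 to 448, CD74, the class II invariant chain, from 1.8 to 266, POU2AF1, a B-cell coactivator, from 4 to 279.8, and CD79B, a B-cell receptor subunit, from 33.9 to 192. Of 34 B lineage genes measured, 15 were raised at 2 h alone (at least 10 counts and 4 times every other column), MS4A1 at 222 among them, and so were 7 of 18 pan-leukocyte genes. Of the T lineage list 1 of 12 (LCK) was raised, and 0 of 12 myeloid and 0 of 9 erythroid genes. Summed counts of the raised B lineage genes were 1664 at 2 h, 18.2 in DMSO and 19.5 at 6 h. At least 10 counts were reached in another column by 9 of the 34 B lineage genes, 10 pan-leukocyte, 4 T lineage, 3 myeloid and 2 erythroid genes. LAYN, a hyaluronan receptor, followed the same course at 54.7, 435 and 38.4 counts. Without blood lineage genes, 38 genes were at least 2-fold higher at 2 h and 35 lower.

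At 6 h losses outnumbered gains, with 152 genes at least 2-fold lower and 75 higher. SEZ6, a neuronal membrane protein, was at -3.63, HS3ST3B1 at -3.13, LRRC10B at -2.97, TACR3 at -2.90, RELN, the secreted guidance protein reelin, at -2.89 and the cadherin CDH6 at -2.86. Of the largest gains, MB (myoglobin) was at 2.45, TNNC1 (cardiac and slow troponin C) at 1.90, MYPN (the sarcomere protein myopalladin) at 1.69 and CAMK2B, a calcium-dependent kinase, at 1.69. EFNA1, an ephrin ligand, was at 2.13 and WNT9A, a Wnt ligand, at 1.65.

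At 24 h, 170 genes were at least 2-fold higher and 213 lower. MB was at 3.80, MYPN at 3.33, UNC45B, a myosin chaperone, at 3.18, MYBPH, a myosin-binding protein, at 3.07, TNNC1 at 3.05 and ABLIM3, an actin-binding protein, at 3.02. STATH, a secreted salivary protein, went from 148 normalised counts in DMSO to 81.5, 32.5, 1 and a listed 0 over the 4 times. TSPAN8, a tetraspanin, was at -4.30, TMCO4 at -4.23, SEZ6 at -4.13, RELN at -3.73 and CDH6 at -3.63.

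At 72 h the change was largest, with 428 genes at least 2-fold higher and 373 lower. MYOM3, a sarcomere M-band protein, was at 6.13, TNNC1 at 5.74, HSPB3, a small heat shock protein of muscle, at 5.65, MYBPH at 5.62, UNC45B at 5.58 and ABLIM3 at 5.03. Next to STATH, the largest decreases were TMCO4 at -4.36, RELN at -4.11, TSPAN8 at -4.09, the scavenger receptor DMBT1 at -3.84 and PPP1R16B, a phosphatase regulator, at -3.82. Library totals gave 347 higher and 452 lower, with the median of all genes at -0.11. In 100 simulations of unchanged groups against the DMSO column, a mean of 12.1 to 13.9 genes passed the size rule per time. Their noise was taken from the clone libraries and held no shift along transcript length.

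Across all 4 times 17 genes were at least 2-fold lower and 17 higher. Among the lower were HS3ST3B1, TACR3, STX11, CNR1 and PRDM12, a transcription factor of sensory neurons (-1.29, -2.72, -2.45 and -3.43). Among the higher were MB, TNNC1, EFNA1, HFE2, which encodes the muscle-expressed BMP co-receptor hemojuvelin (1.85, 1.55, 2.17 and 4.54), and BCL6, a transcriptional repressor (1.80, 1.62, 1.82 and 1.52).

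**Figure D1:**
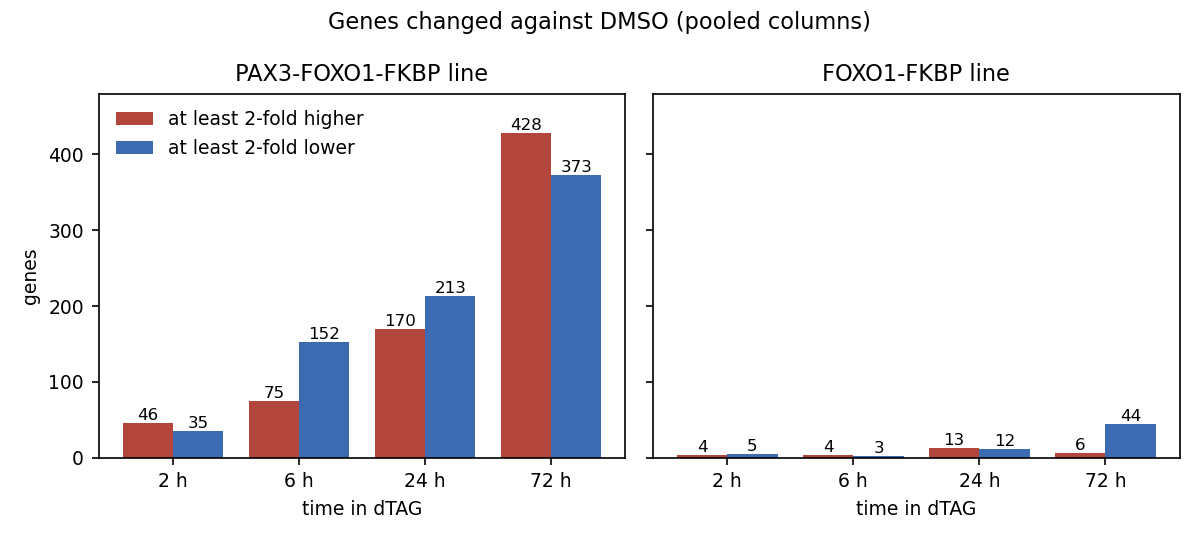
Bars give the number of genes at least 2-fold higher (red) or lower (blue) than in DMSO at each time in dTAG, per line, from 1 pooled column per condition. The PAX3-FOXO1-FKBP line went from 46 and 35 genes at 2 h to 428 and 373 at 72 h, and the FOXO1-FKBP line had 44 lower and 6 higher at 72 h.

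The trend test over time called 296 rising and 268 falling genes of 12335 in the PAX3-FOXO1-FKBP line (edgeR quasi-likelihood, adjusted p under 0.05). Without the 72 h column it called 118 in all, and DESeq2 called 988. These p-values rest on scatter between pooled columns.

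Published PAX3-FOXO1 targets were lower as a group at each time. The median of the 31 measured was -0.40, -0.76, -0.72 and -0.89 at 2, 6, 24 and 72 h, below every one of the 10000 random lists at each time, and 1, 11, 12 and 14 of them were at least 2-fold lower. On the trend, camera gave an adjusted p of 2.4e-16 (adjusted p = 0.406 with an estimated correlation), with 12 members falling, 2 rising and 20 passing when adjusted over the list alone. NOS1, a neuronal nitric oxide synthase, fell by 2.81 on the log2 scale at 72 h (edgeR trend adjusted p = 0.00142) and POU4F1, a sensory neuron factor, fell by 3.17 (0.00173). RASSF4 rose to 1.96 (0.00194) and MYOG (myogenin), the regulator of terminal myogenesis, to 1.85 (0.00228).

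Muscle contractile and differentiation genes were higher as a group at each time, though 11 members were below 0 at 2 h. Their median over 44 measured genes was 0.39, 0.47, 0.97 and 2.38, above all random lists at each time, and 33 were at least 2-fold higher at 72 h. Camera on the trend gave an adjusted p of 2.91e-54 (adjusted p = 0.354 with an estimated correlation). Of the members 28 rose, 0 fell, and 37 passed when adjusted over the list alone. Cardiac actin ACTC1 rose to 2.32 at 72 h and KBTBD10, a sarcomere-associated Kelch protein, to 2.60 (both edgeR adjusted p = 0.00142). UNC45B had an adjusted p of 0.00196, and MYLPF, the fast myosin light chain, rose to 4.43 (0.00219).

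Of 9 myogenic transcription factors, MYOG rose and MEF2C, a partner of myogenic factors, rose to 2.02 at 72 h (edgeR adjusted p = 0.0322). The group median stayed at -0.11, -0.05, 0.19 and 0.09, with a camera adjusted p of 0.202. SIX4 was at -0.67 at 72 h and did not pass the trend test.

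YAP/TEAD-responsive genes had a median of 0.85 at 72 h (7 of 15 at least 2-fold higher, camera adjusted p = 5.64e-06, and adjusted p = 0.406 with an estimated correlation). ANKRD1, a muscle ankyrin repeat protein, rose to 3.11 (edgeR adjusted p = 0.0197), while CTGF stood at 2.44 and missed the threshold (0.0541). Notch pathway genes had a median of 0.46 at 72 h (14 genes, camera adjusted p = 0.00044, and adjusted p = 0.354 with an estimated correlation). Fry passed for this list (0.00215) but for no other list that camera called on this trend, with 0.115 for published targets, muscle genes and YAP/TEAD-responsive genes, 0.162 for S phase and 0.322 for G2/M. The bHLH repressors HES6 and HEY1 rose to 1.23 (edgeR adjusted p = 0.00521) and 1.81 (0.0199). ERK feedback and immediate-early genes had a median of -0.55 at 6 h and 0.05 at 72 h (17 genes, camera adjusted p = 0.0514). ETV5, a factor downstream of receptor kinases, fell by 1.20 at 72 h (edgeR adjusted p = 0.00786). DUSP6, an ERK phosphatase, was at -2.44 at 24 h but did not follow a straight trend (0.0788), and EGR1 stood at 2.02 at 72 h (0.0653).

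Proliferation genes were slightly lower late. All 24 S phase genes were below their DMSO level at 72 h with a median of -0.23, and the 24 G2/M genes had a median of -0.30. Camera gave 0.00534 for S phase and 0.0135 for G2/M (adjusted p = 0.581 for each with an estimated correlation). Cyclin E gene CCNE1 fell by 0.89 (edgeR adjusted p = 0.0265) and the kinetochore motor CENPE fell by 0.69 (0.0284), the only called member of each list.

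Interferon-stimulated genes had a median of 0.87 at 72 h (10 genes, camera adjusted p = 0.0135, and adjusted p = 0.518 with an estimated correlation), and IFIT1, an RNA-binding antiviral protein, rose to 2.04 (edgeR adjusted p = 0.0446). ATF4-responsive genes had a median of -0.16 (16 genes, camera adjusted p = 0.0458, and adjusted p = 0.518 with an estimated correlation). Within them TRIB3, a stress-induced pseudokinase, fell by 1.57 (edgeR adjusted p = 0.0047) and the serine synthesis gene PSAT1 fell by 0.63 (0.0345). The neuronal list was called downward by camera (adjusted p = 0.0254, and adjusted p = 0.45 with an estimated correlation) although its median was 0.36 at 72 h. POU4F1 and the adhesion gene NRCAM fell (NRCAM by 1.71, edgeR adjusted p = 0.00267) while the tubulin TUBB3 rose to 1.39 (0.0289).

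The other lists did not pass camera. FOXO-responsive genes had a median of 0.05 at 72 h (camera adjusted p = 0.125), with the ubiquitin ligase FBXO32 up at 2.30 (edgeR adjusted p = 0.0295) and ERBB3 at 1.44 (0.0045). The camera adjusted p was 0.975 for p53-responsive genes (GDF15 at -0.72), 0.306 for the BCL2 family (BMF at 1.18), 0.645 for ribosome biogenesis and MYC-responsive genes (MYC at -0.73) and 0.142 for cholesterol synthesis genes (MVD at 0.84). It was 0.122 for hypoxia-responsive genes, whose NDRG1 fell by 1.40 (edgeR adjusted p = 0.0215), and 0.166 for heat shock genes, whose HSPB1 rose to 0.92 (0.0162). For the extracellular matrix list it was 0.509, with COL1A1 up at 2.43 (edgeR adjusted p = 0.016), and for the epithelial list 0.122, with KRT18 at -1.03. Of the endothelial list VWF alone was measured, and it fell by 1.74 at 72 h (edgeR adjusted p = 0.0274). The histone HIST1H1C was at 0.69, and 0 blood markers of the fixed list and 0 mitochondrially encoded mRNAs reached the minimum count.

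**Figure D2:**
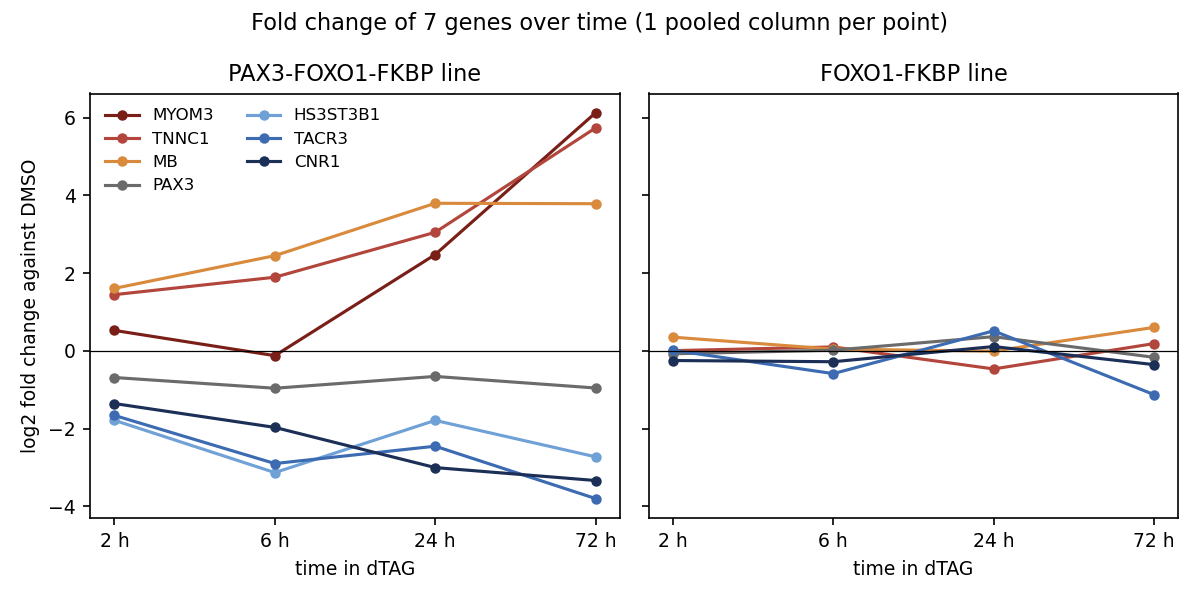
Lines give the log2 fold change against DMSO of 7 genes by time in dTAG, 1 pooled column per point, in each line. In the PAX3-FOXO1-FKBP line MYOM3 reached 6.13 and TNNC1 5.74 at 72 h while TACR3 reached -3.80; MYOM3 and HS3ST3B1 are not drawn for the FOXO1-FKBP line, where they were under the minimum count.

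Fewer genes passed 2-fold in the FOXO1-FKBP line under the same compound. Of 11982 genes, 4 were at least 2-fold higher and 5 lower at 2 h, 4 and 3 at 6 h, 13 and 12 at 24 h, and 6 and 44 at 72 h. After GC and length correction these were 10 and 4 of 10777 at 24 h, and 3 and 27 at 72 h. At 2 h the zinc exporter SLC30A1 was at 1.27, the protease CTSK at 1.17 and the chaperone DNAJB4 at -1.04. Among the remaining 2 h and 6 h genes, named after their values were seen, were the read-through names INS-IGF2, PPAN-P2RY11, SERF2-C15ORF63, C1orf151-NBL1, COMMD3-BMI1 and PALM2-AKAP2, the ribosomal protein gene RPL21 and C21orf88. At 24 h PCDHGA6, a protocadherin, was at 1.33, ZBED6 at 1.30, FAM106A at 1.22, OPRD1 at 1.13, PROX1 at 1.10 and PCDHB8 at 1.04. RNF5, a ubiquitin ligase, was at -2.44, the nuclear RNA MALAT1 at -1.11, HMGN5 at -1.08 and FAM133B at -1.02. Library totals gave 22 higher and 9 lower at 24 h, and 4 and 5 at 6 h.

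At 72 h the lower genes of the FOXO1-FKBP line were ZNF354C at -1.86, the coactivator NCOA2 at -1.76, the kinase HIPK3 at -1.58, FAM171B at -1.53, ZNF192 at -1.52 and TGFBRAP1 at -1.49. TICAM2, an adaptor of innate signalling, was at 1.10. The other 5 higher genes, named after their values were seen, were INS-IGF2, PPAN-P2RY11, LOC728640, RAD51L3-RFFL and SPDYE7P. The 44 lower genes had a median transcript length of 5326 nt against 3521 nt for all genes. Their median change at 72 h was -1.27, and -1.14 after correction for GC content and length, while at 24 h it was 0.502. Across genes, changes in this column followed length with rho = -0.51 and GC content with rho = 0.495 (genes are not independent replicates). Length was followed in other columns too, at rho = -0.364 at 6 h and 0.306 at 24 h in this line. In the PAX3-FOXO1-FKBP line rho with length was -0.31, -0.25, -0.00722 and -0.279 at 2, 6, 24 and 72 h. Past 2-fold there after GC and length correction were 73, 198, 351 and 698 of 11084 genes. Of the 44 lower genes of the FOXO1-FKBP line, 43 were measured in the PAX3-FOXO1-FKBP line. Their median there at 72 h was -0.764, and 14 were at least 2-fold lower.

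The trend test called 0 genes of 11982 in the FOXO1-FKBP line (edgeR), with 576 at an unadjusted p under 0.05. DESeq2 called 1 (HNRNPA1P10), and edgeR called 1 without the 72 h column (H3F3A), both named after their values were seen. The published targets had medians of -0.03, -0.08, 0.10 and -0.08 there and the muscle genes 0.04, -0.01, 0.02 and 0.07. Heat shock genes were lower at 2 h with a median of -0.57 over 10 genes, all below 0, among them HSPA1B (-0.82), HSPA8 (-0.76), DNAJB1 (-0.70) and HSPH1 (-0.61). ATF4-responsive genes were slightly higher at 2 h, with a median of 0.17 and 15 of 16 above 0. YAP/TEAD-responsive genes had a median of -0.21 at 72 h.

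Set directly against each other, the lines differed by at least 2-fold in their change for 40 genes upward and 37 downward at 2 h, 55 and 102 at 6 h, 125 and 212 at 24 h, and 333 and 252 at 72 h, of 11766. Library totals gave 31 and 52 at 2 h. The difference in slope was tested with edgeR and passed for 135 genes upward and 112 downward of 11767. It passed for 59 genes without the 2 h columns, 48 without the 72 h columns and 525 with DESeq2. Muscle genes differed upward (camera adjusted p = 2.08e-49, 19 members called, 31 adjusted over the list alone) and published targets downward (1.43e-14, 8 members lower and 2 higher, 19 adjusted over the list alone). For both, adjusted p = 0.133 with an estimated correlation. YAP/TEAD-responsive genes (1.15e-07) and Notch pathway genes (0.0066) also differed upward, again with adjusted p = 0.133 with an estimated correlation. Cholesterol synthesis genes (0.0309) differed upward and S phase genes (0.035) downward, each with adjusted p = 0.612 with an estimated correlation. Some lists that camera called in the PAX3-FOXO1-FKBP trend did not pass for the line difference. These were G2/M, interferon-stimulated and ATF4-responsive genes (camera adjusted p = 0.117 each) and neuronal genes (0.104).

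Of the 227 genes at least 2-fold changed at 6 h, 189 (83.3%) were changed the same way at 72 h, 65 upward and 124 downward. Independent lists of these sizes would share 2.6 and 4.6 genes. Simulated unchanged groups shared 1.52 and 0.51, but a mean of only 13.3 genes passed there at 6 h and 13.9 at 72 h. The shared count of such short lists cannot be set against 189. Of the 81 changed at 2 h, 54 (66.7%) were changed the same way at 72 h but 37 (45.7%) at 24 h. The 81 include B lineage and leukocyte genes raised at 2 h alone. Without blood lineage genes, 54 of 73 (74%) were changed the same way at 72 h. Between 2 and 24 h r was 0.36 across genes, and 82.7% of the 81 kept their sign. Changes at 6 h and 72 h had r = 0.728 across genes and a covariance of 0.15. In simulated unchanged groups, 2 and 24 h had r = 0.499 and 94.3% kept their sign. For 6 and 72 h, simulated r was 0.498 and the covariance 0.0278. That agreement comes from the shared DMSO column, so simulated r and sign are no expectation for changed genes. The DMSO column cannot be split, so part of the overlap may come from it. The 2, 6 and 72 h columns also followed transcript length (rho = -0.31, -0.25 and -0.279), and the 24 h column barely did (-0.00722). After GC and length correction 65.8% of 2 h genes and 79.8% of 6 h genes were changed the same way at 72 h. Without the DMSO column, the genes lower at 2 h moved by a median of 0.173 from 6 to 24 h. From 24 to 72 h they moved by -0.611. The genes lower at 6 h moved by -0.0578 and -0.217, and those higher at 6 h by 0.118 and 0.626.

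Genes changed at 6 h of fusion loss were followed in the FOXO1-FKBP line, where the tag is on wild-type FOXO1. The 125 lower genes measured there had medians of -0.03, -0.16, 0.03 and -0.18 over the 4 times and the 57 higher ones 0.05, 0.10, -0.03 and 0.12. Camera on the trend gave 0.00669 downward and 0.0231 upward. For both, adjusted p = 0.904 with an estimated correlation. Fry passed for neither list (adjusted p = 0.982 for both), and their median slopes were -0.0119 and 0.0181. Camera on lists taken at 2 h gave 0.855 and 0.44. Across 11766 genes the changes of the 2 lines had rho = 0.116, 0.37, -0.00105 and 0.391 at 2, 6, 24 and 72 h. After GC and length correction rho was 0.313 at 6 h and 0.353 at 72 h. Part of the change at 6 and 72 h thus went the same way in both lines.

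The clones ask how far tagging and cloning alone changed untreated cells. Of 14175 genes, edgeR called 3562 higher and 3161 lower in clone 4 than in parental Rh30, 3942 and 3432 in clone 10, 3755 and 3561 in clone 11, and 3946 and 3508 in clone 12. At least 2-fold changes numbered 2767, 3180, 2995 and 3238. In all 4 clones, 129 genes were called at least 2-fold higher and 465 lower. The 4 comparisons share the 2 parental libraries, so part of this agreement may come from them. Changes followed GC content across genes (rho = 0.546, 0.594, 0.662 and 0.604). After GC and length correction the calls were 5791, 5952, 5310 and 5958 of 12587 genes, and 64 and 169 were at least 2-fold higher or lower in all 4. Only part of these were the same genes. Of the 6723, 7374, 7316 and 7454 genes called without correction, 4062, 4102, 3537 and 4093 were called with it. Genes without a GC value were not tested with it. Library totals gave 2494 higher and 3983 lower in clone 4, 2599 and 4713 in clone 11, and 2646 and 4576 in clone 12, where the median of all genes under that scaling was -0.125, -0.231 and -0.192. Each parental library mattered: without parental replicate 1 the calls numbered 3962, 4658, 4734 and 4818, and without replicate 2 they numbered 3923, 4586, 4738 and 4758.

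In clone 4, KRT18, a keratin of simple epithelia, went from a mean normalised count of 1.91 to 1335, KRT8 rose by 5.53 on the log2 scale, the surface glycoprotein THY1 by 7.84, the mineralisation inhibitor MGP by 6.95 and ARHGDIB by 5.57. CPXM1 had 0 counts in parental cells and was at least 186-fold higher. NRK, a kinase, was at least 227-fold lower, the cancer-testis gene MAGEA3 at least 124-fold, FAM199X at least 56.5-fold, TMSB15B, a thymosin, at least 33.3-fold and the sorting receptor SORCS2 at least 29.9-fold. LAMA1, a laminin chain, went from 757.3 to 0.5788. Standard errors of these 12 log2 changes were 0.296 to 0.806 (n = 2 per group, edgeR adjusted p at most 8.79e-05).

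In clone 10, GABRA3, a GABA receptor subunit, went from 0.3637 to 324.2 and KRT18 from 1.91 to 867. THY1 rose by 8.85, the collagen-binding integrin ITGA11 by 6.99, the amino acid transporter SLC7A8 by 6.75 and MAGEA6 by 6.74. FXYD5, an ion pump regulator, was at least 106-fold lower, MAGEC2 at least 57.1-fold, the homeobox gene EN2 at least 28.2-fold, AP5B1 at least 24.8-fold and ITIH5 at least 11.4-fold. MAGEB1 went from 127.1 to 0.455. Standard errors were 0.299 to 0.918 (edgeR adjusted p at most 8.97e-05).

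Clone 11 gained KLHDC7B (4.45), the exchanger SLC24A3 (4.28), the muscle ligase TRIM54 (4.18), the cytokine receptor CNTFR (3.97), the bHLH factor OLIG1 (3.82) and NUPR1 (3.79). Of its largest decreases, the cancer-testis gene MAGEA3 was at least 125-fold lower, MAGEC2 went from 174.6 to 0.6675, MAGEC1 from 55.63 to 1.335 and MAGEA6 from 6.641 to 0 (at least 1.98-fold). The teneurin ODZ2 went from 143.5 to 0.4482 and PRICKLE1 from 75.64 to 1.564. Standard errors were 0.291 to 1.12 (edgeR adjusted p at most 0.0034).

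Clone 12 gained THY1 (8.70), SLC7A8 (4.93), EGFL7 (4.66), the muscle stress gene ANKRD2 (4.42), the calcineurin regulator RCAN2 (4.35) and KISS1 (4.32). FXYD5 was at least 94.4-fold lower, FAM199X at least 55.5-fold, CLEC11A at least 42.6-fold, TMSB15B at least 32.7-fold and the regulator PRDM16 at least 28.9-fold, while NRK went from 762.4 to 0.5234. Standard errors were 0.331 to 0.903 (edgeR adjusted p at most 0.000193). PAX3 was called in no clone, at 0.39, 0.26, -0.47 and -0.42 in clones 4, 10, 11 and 12 (edgeR adjusted p = 0.321, 0.512, 0.234 and 0.282). FOXO1 was at -0.58, -0.81, -1.06 and -1.30 (adjusted p = 0.0584, 0.0134, 0.0034 and 0.00115). Without parental replicate 1, parental replicate 2 or clone 10 replicate 2, FOXO1 in clone 10 was at -0.83, -0.80 and -0.62 and lost its call. Without clone 4 replicate 1, FOXO1 in clone 4 was called at -0.90, and without clone 4 replicate 2 PAX3 there was called at 0.83.

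Muscle contractile and differentiation genes were higher than parental in all 4 untreated clones. Their medians over 46 genes were 0.77, 0.92, 0.74 and 0.95 in clones 4, 10, 11 and 12, with camera adjusted p = 1.68e-06, 6.55e-06, 0.00334 and 3.67e-05. These were p = 0.777, 0.547, 0.746 and 0.88 with an estimated correlation, and after GC and length correction 0.125 in clone 11. The corrected medians were 0.62, 0.70, 0.19 and 0.51. Members called higher and lower were 29 and 2, 29 and 1, 22 and 1, and 25 and 2, and 31, 30, 22 and 31 were called when adjusted over the list alone. The fetal myosin gene MYH8 was at 3.40, 2.71, 3.11 and 2.57, and the muscle intermediate filament DES at 1.79 in clone 10, 1.18 in clone 11 and 1.60 in clone 12.

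Published targets were lower in clone 12 with a median of -0.70 over 33 genes, 19 called lower and 4 higher and 23 adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.88 with an estimated correlation). TFAP2B, a neural crest factor, was at -2.10 there, FOXF1 at -3.32, CDH3 at -1.65 and CNR1 at -1.65. In clones 4, 10 and 11 the list had camera adjusted p = 0.908, 0.276 and 0.881. After GC and length correction it was called lower in clone 10 too (median -0.55, camera adjusted p = 0.000924).

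Extracellular matrix and fibroblast genes were higher in clone 10, with 13 of 15 called (camera adjusted p = 1.71e-09, and adjusted p = 0.228 with an estimated correlation), the collagens COL3A1 at 5.49 and COL1A1 at 2.04 among them. They also passed in clone 4 (0.0237) and clone 12 (0.0277), with p = 0.777 and 0.88 with an estimated correlation. Epithelial markers were higher in clone 4 (4.3e-07, and p = 0.253 with an estimated correlation) and clone 10 (4.14e-05, and p = 0.228), with KRT8 and KRT18 called in both and CLDN4 in clone 10. YAP/TEAD-responsive genes were higher in clone 4 (0.0237) and clone 10 (0.00801) and lower in clone 11 (0.0193), with p = 0.788, 0.672 and 0.746 with an estimated correlation. Their member MYOF, a membrane repair protein, was at 2.19, 2.17 and -1.53. ATF4-responsive genes were higher in clone 11 (0.0153, and p = 0.767 with an estimated correlation) and clone 12 (0.0222, and p = 0.88), with the serine synthesis gene PHGDH at 1.25 and 1.54. Interferon-stimulated genes were higher in clone 10 (0.0207, and p = 0.547 with an estimated correlation), where OAS3 was at 5.46 and BST2 at -5.47. S phase genes were higher in clone 4 (0.021, and p = 0.777 with an estimated correlation), with the helicase gene MCM2 at 1.12. GC and length correction ended the calls of extracellular matrix genes in clone 4 (camera adjusted p = 0.234, median 0.45 before and 0.02 after) and clone 12 (0.0704, 0.25 and 0.14) and of ATF4-responsive genes in clone 12 (0.112, 0.75 and 0.48). It also ended those of S phase genes (0.0535, 0.44 and 0.285) and YAP/TEAD-responsive genes (0.0535, 0.71 and 0.56) in clone 4. With it, Notch pathway genes (0.00345) and ERK feedback and immediate-early genes (0.0243) were called lower in clone 11. With the replicate block, G2/M genes were called lower in clone 10 (0.0226) and clone 11 (0.0309). Without either, the remaining lists passed camera in no clone.

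The genes lower at 6 h of fusion loss were lower in clone 12. The 152 genes had a median of -0.995 there, outside the central 95% of random lists (-0.176 to 0.161), with 93 called lower and 5 higher, and 100 adjusted over the list alone (camera adjusted p = 9.5e-16, and adjusted p = 0.127 with an estimated correlation). With genes near 0 set at their bound the median was -0.97. In clones 4, 10 and 11 the medians were 0.25, -0.00 and -0.14 (camera adjusted p = 0.0765, 0.226 and 0.474). In clone 4 the median lay above the central 95% of random lists (-0.129 to 0.169). With the replicate block the list was called higher there (camera adjusted p = 0.0337). The 74 genes higher at 6 h had medians of 0.17, 0.95, 0.15 and 1.35 in clones 4, 10, 11 and 12, called higher in clone 10 (camera adjusted p = 0.000411, and adjusted p = 0.133 with an estimated correlation) and in clone 12 (4.46e-09, and 0.0242). In clones 4 and 11 the camera adjusted p was 0.259 and 0.943.

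**Figure D3:**
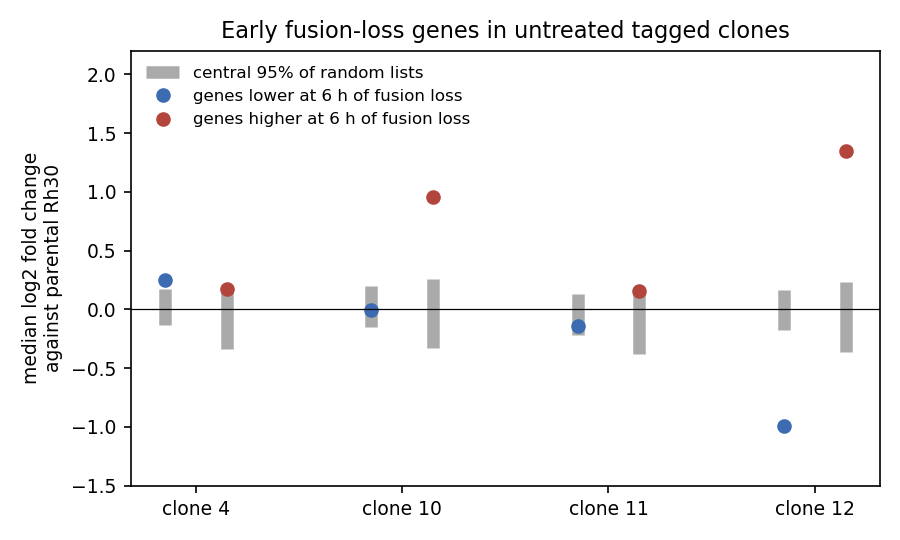
Points give the median log2 fold change against parental Rh30 of the genes at least 2-fold lower (blue) or higher (red) at 6 h of fusion loss, per untreated clone, and grey bars the central 95% of 10000 random lists. Clone 12 shows the lower list at -0.995 and the higher list at 1.35.

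In clones 4 and 12, 7 neighbouring X-linked genes were near 0, a run singled out after the values were seen. They were RAB9B, TMSB15B, MCART6, ZCCHC18, LOC286437, FAM199X and NRK, at 26.8 to 762.4 normalised counts in parental cells. Raw totals over both libraries were 0 to 2 in clone 4 and 0 to 1 in clone 12. On either side, MORF4L2 was at 13870 in parental cells, 9854 in clone 4 and 10050 in clone 12, and MUM1L1 at 94.6, 41.7 and 41.1. In clones 10 and 11 NRK was at 929.2 and 570.7.

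**Figure D4:**
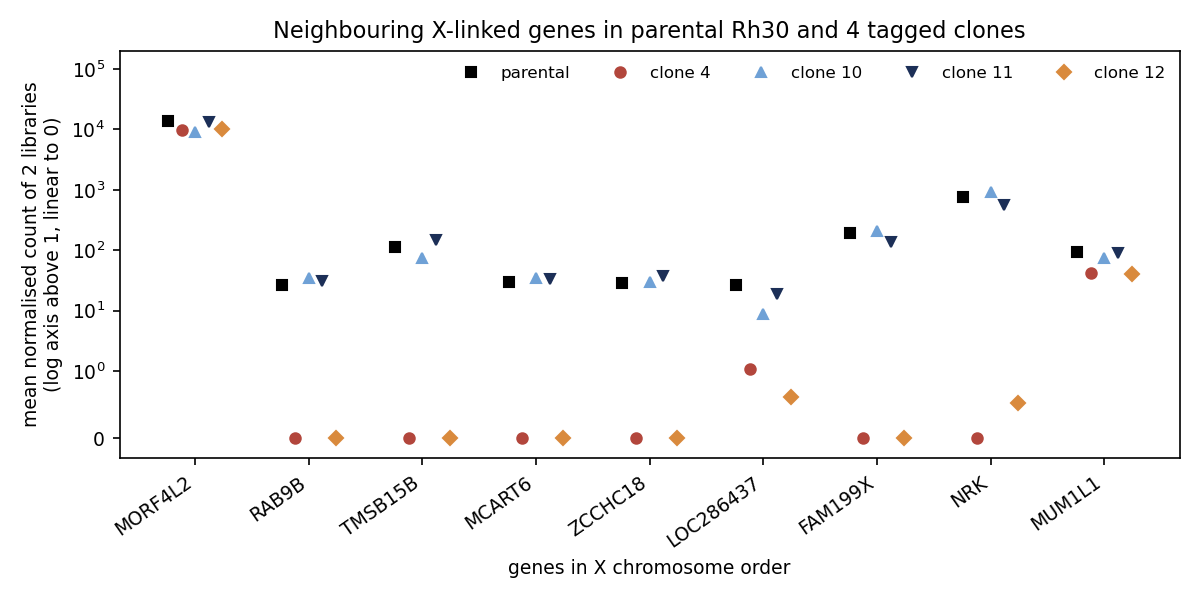
Points give the mean normalised count of 2 libraries (log axis above 1, linear to 0) of the 7 genes of the run and the gene on either side, in X chromosome order. Clones 4 and 12 lie near 0 from RAB9B to NRK, while parental cells lie at 26.8 to 762.4 there.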

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

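The tests of the difference in trend between the lines, of differences between clones and of explanations below were all chosen only after the results were seen.

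The trend over time differed between the PAX3-FOXO1-FKBP and FOXO1-FKBP lines for 247 of 11767 genes (edgeR, adjusted p under 0.05), tested as an interaction over the pooled columns. Among them were 19 muscle genes with the higher slope in the first line, and 8 published targets with the lower slope and 2 with the higher.

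The clones differed from each other as well as from parental Rh30. The number of genes whose difference from parental cells differed between 2 clones (edgeR) was 3374 for clones 4 and 10, 5057 for clones 4 and 11, and 4326 for clones 4 and 12. It was 5954 for clones 10 and 11, 5005 for clones 10 and 12, and 3905 for clones 11 and 12. After GC and length correction the pairs gave 4658 to 6040. These fits had no replicate block. Deviations of same-numbered libraries had r = 0.568 for clones 4 and 10, 0.186 for 4 and 11, and 0.173 for 10 and 11. A shared replicate effect among these clones was thus not taken into account.

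Genes lower early in fusion loss were called lower as a group in clone 12 and in no other clone, a call lost with an estimated correlation (camera adjusted p = 0.127). GC content and transcript length were argued against as the whole cause, since after correction the median in clone 12 was still -0.77 (camera adjusted p = 3.51e-15 at the preset correlation). Lower activity of the tagged fusion in every clone cannot be decided. In clone 4 the median of this list was 0.252 (camera adjusted p = 0.0765), which goes against it. Muscle genes, higher after fusion loss, were higher in clone 4 too (median 0.77, camera adjusted p = 1.68e-06, and 0.777 with an estimated correlation), which goes with it. Lower activity in clone 12 itself remains a candidate explanation, because genes higher at 6 h of fusion loss were also higher there (median 1.35) and FOXO1 mRNA, which includes the fusion's part, was called lower at -1.30 (edgeR adjusted p = 0.00115), but neither is particular to clone 12: the higher list was called in clone 10 (0.953, camera adjusted p = 0.000411), and FOXO1 in clones 10 (-0.81, edgeR adjusted p = 0.0134) and 11 (-1.06, 0.0034). PAX3 mRNA was at -0.42 without a call, fusion protein was not measured, and an unrelated drift of this clone stays open; measuring fusion protein and its binding at these genes in clone 12 and parental cells would test it.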

How the results depend on the processing

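Added after the data were seen were all trend tests and their alternatives, the filters on a mean of 200 and on 2 or more columns, genes listed at 0 kept, blood lineage genes left out, GC and length correction, all persistence alternatives and the block in the early lists. Of 236 named time-course values, 1675 recomputations moved by less than counting error and 17 moved. Of 56 named clone values, 678 recomputations kept their call, 14 gained one and 3 lost one, and 0 reversed.

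The size rule depends on the count filter. With no filter the PAX3-FOXO1-FKBP line had 441, 512, 732 and 1378 genes at 2, 6, 24 and 72 h, the FOXO1-FKBP line 108, 101, 151 and 201, and the line difference 376, 476, 771 and 1084. At a mean count of at least 200 these were 30, 140, 250 and 518, then 1, 3, 8 and 15, then 20, 84, 192 and 350, with fewer genes tested. GC and length correction gave 14 genes at 24 h and 30 at 72 h in the FOXO1-FKBP line. The cause was not tested.

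The trend without the 72 h columns gave 118 genes in the PAX3-FOXO1-FKBP line, 1 in the FOXO1-FKBP line and 48 for the difference. Without the 2 h columns the difference gave 59. Fewer columns leave fewer residual degrees of freedom. This alone does not account for the 118, since the PAX3-FOXO1-FKBP line without its 2 h column still gave 462 genes, against 564 with all columns. DESeq2 gave 988, 1 and 525, and the cause was not tested. At 1.5-fold, 75.6% of 6 h genes were changed the same way at 72 h.

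In the clones, leaving out parental replicates gave 3923 to 3962 genes in clone 4, 4586 to 4658 in clone 10, 4734 to 4738 in clone 11 and 4758 to 4818 in clone 12. Leaving out a clone library gave 6134 to 6253, 5310 to 5404, 4915 to 7136 and 5178 to 5468, the lone library being assumed to vary like the other groups. DESeq2 gave 6449, 6787, 7040 and 7180.

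With an estimated correlation, 0 of 17 list calls in the clones, 0 of 9 in the PAX3-FOXO1-FKBP trend and 0 of 6 in the line difference remained. The estimates were up to 0.702 between genes of a list. Fry in the clones passed for the lists that camera called, at most at 0.0431, except ATF4-responsive genes (0.0635 in clone 11 and 0.065 in clone 12). It also passed for lists that camera did not call. In the line difference fry missed S phase and cholesterol synthesis genes (0.234 each) and passed for the others that camera called (at most 0.0416). With an estimated correlation, camera on the early lists gave 0.133 for higher genes in clone 10, 0.127 for lower genes in clone 12 and 0.904 for both lists in the FOXO1-FKBP line. At the preset correlation, lists from 2 h gave 0.855 for lower genes and 0.44, in the opposite direction, for higher genes in that line.

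Deviations of same-numbered libraries had r = 0.0845, 0.00518, 0.568, -0.0361, 0.186 and 0.173 over the 6 pairs of parental cells and clones 4, 10 and 11, listed as parental with 4, parental with 10, 4 with 10, parental with 11, 4 with 11 and 10 with 11. The numbers are not shown to pair parental cells with clones, and a shared replicate effect among the 3 clones stays open. With the replicate block the calls were 7046, 7705 and 7689 in clones 4, 10 and 11, and 6221, 6343 and 5746 with GC and length correction as well. Under the block, lower genes at 6 h passed in clone 4 (camera adjusted p = 0.0337, direction up), and lists called numbered 15 against 13. No paired analysis was possible for the time course because its columns are pooled, and clone 12, with other replicate numbers, was left out of the block. DESeq2, leave-one-out and 4-library fits at single times were not run for the same reason.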

Other observations

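The tests in this part were all chosen only after the results were seen, and marker lists were written after B-cell genes had been noticed.

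Some genes stood apart in 1 time-course column. At least 10 counts and 4 times every other column were reached by 120 genes in the PAX3-FOXO1-FKBP 2 h column (0.0226% of its counts) and by 32 in its 72 h column, against 0 or 1 in each of the other 8 columns. PTPRC, the leukocyte phosphatase, was at 186 normalised counts at 2 h, the B-cell lectin CD22 at 95.3 and IRF8 at 107.

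B lineage transcripts at 2 h may come from cells, RNA or reads of the B lineage, because 15 B lineage genes were raised in that column alone. Mixed blood cells are argued against, since of the T lineage, myeloid and erythroid genes 1 was raised. Ordinary B cells with MHC class II cannot be told apart from other cells of the lineage, since HLA-DRA, HLA-DRB1, HLA-DPA1, HLA-DPB1 and HLA-DQA1 were listed at 0 there but near 0 in every column, which can be failed estimates. CD74 and HLA-DMB (26.2) were raised, while HLA-DMA was not (11.65, and 12.07 in DMSO). A response of the cells to 2 h of fusion loss cannot be told apart from RNA of the B lineage: at 6 h these genes were at 1.17% of their 2 h count, which a brief response could also give; reads of each of the 2 pooled samples, searched for rearranged immunoglobulin sequences, would test this and show whether 1 or both carried them.

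The run of X-linked genes near 0 in clones 4 and 12 is argued not to be chance position, since in 1000 shuffles of gene positions the longest run was 2. Fewer reads in these clones are argued against, since clones 10 and 11 kept these genes at no less than 33.2% of parental and MORF4L2 beside the run stayed high. Loss of a DNA segment could give 7 neighbouring genes near 0, and cannot be told apart from silencing of the region, because RNA alone was measured. Near 0 in both clones were 23 genes, against 0.213 if the clones were independent. The 23 include the 7 of the run, both clones were compared with the same parental libraries, and other pairs were not counted. Other pairs shared genes at 0 too, FXYD5 in clones 10 and 12 and MAGEA3 in clones 4 and 11. A shared subclone of parental cells is possible, but this count cannot decide it. DNA sequencing of the region in parental cells and clones would test segment loss and a shared subclone.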
